A study of Homo sapiens with 12 samples.

How the data were processed

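Gene expression was measured by RNA sequencing in 12 libraries of Huh7, an established human hepatocellular carcinoma cell line, in 4 groups of 3 libraries: solvent control, disulfiram, thalidomide and both drugs together. Disulfiram is an inhibitor of aldehyde dehydrogenases whose copper-bound metabolite is known to bind NPLOC4, an adaptor of the p97 segregase. Thalidomide binds cereblon, the substrate receptor of a ubiquitin ligase. Doses with their units, the length of treatment and the read depth are not given in the sources used here. The protocol text of the labels describes patient tissue and droplet-based barcoding of single cells, which does not match 12 columns of a cell line with 1 value per gene each, so the library preparation is not known. Whether reads came from whole transcripts or from 3' ends, and from which strand, is therefore not known either, and values of overlapping or antisense genes and of near-identical copies are uncertain.

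The deposited table holds TPM per gene, a length-scaled share of all transcripts, computed by the authors, and all columns sum to the same total. HISAT2 2.0, StringTie 1.3.0 and the genome build hg38 are named per the submitters' processing notes, which state neither the annotation nor filters. The table lists 59191 features, of which 58884 carry an Ensembl gene identifier and 307 are assembled loci without one. Symbols and coordinates were taken from GENCODE 29 (hg38), which holds 58611 of the identifiers. TPM keeps no count of reads, so the depth is unknown and no counting interval can be given. As shares of a fixed total, TPM values also shift together when a few abundant transcripts change, and values are rounded to 2 decimals, so low genes are coarse.

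From the deposited TPM, log2(TPM + 1) was computed, with TPM of at least 1 in at least 3 of the 12 libraries required for testing, which left 15352 genes. The pseudocount makes fold changes of genes with low TPM smaller than the ratio of their means. Group means were compared with limma 3.58.1 (R 4.3.3), using its mean-variance trend, all 12 libraries in one fit, two-sided moderated tests and Benjamini-Hochberg adjustment over the genes tested, with an adjusted p below 0.05 as the threshold. The comparisons were each drug and the combination against control, the combination against each drug, disulfiram against thalidomide, and the interaction (the combination minus both single drugs plus control on the log2 scale). No replicate term was used, since nothing in the labels says that a number is a shared day, and no label says that replicates are separate cultures. The p-values therefore measure only the spread between these libraries.

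A total of 40 gene lists and the rules for comparisons and named genes were fixed before the data were examined. Lists with at least 5 tested members (39) were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. Fry, which asks whether a list's own members move 1 way on balance, was run beside them. Members past the threshold were counted over all genes and adjusted over the list alone. Named genes are the 6 largest rises and 6 largest falls per comparison with control, and 4 and 4 in the other comparisons with the combination. They had to pass the threshold, have a mean TPM of at least 5 in 1 compared group, show no overlap of the libraries of the compared groups and have a plain symbol. From each list described, up to 4 members with the largest change past the threshold were taken, or 2 with the highest TPM where none passed, and the text names mainly those that stayed past the threshold when any 1 library was left out. ALDH2, ALDH1A1, NPLOC4, CRBN, AFP and ALB were always included. Some genes that these rules picked are not reported here. Overlap of calls was set beside 100 simulated sets of unchanged groups sharing the same controls.

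The fits were tested on simulated data drawn for 15352 genes, of which 70 were changed 1.5-fold, 70 2-fold and 60 4-fold. The changed genes were picked only among those above a minimum expression level. The shares below therefore say nothing of genes with low TPM, whose fold changes the pseudocount makes smaller. For disulfiram against control, 55.7% of genes changed 1.5-fold, 94.3% of those changed 2-fold and 100.0% of those changed 4-fold were called, with 7 unchanged genes called. For the combination against control the shares were 42.9%, 91.4% and 100.0%, with 10 unchanged genes called. For the interaction they were 24.3%, 71.4% and 98.3%, with 4 unchanged genes called. A shifted list was called in all 3 comparisons, and 0, 1 and 0 of the others among 21 simulated lists were called. Noise was drawn separately for each gene, so this says nothing of false calls among lists whose genes vary together. In the real data, other splits of the disulfiram and control libraries called up to 16 lists. Those splits mix both groups unevenly and can keep part of a real difference, so this is not a count of false calls.

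Alternatives were median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, no filter on low values, a mean TPM of at least 5, the replicate number as a block, only the compared groups in the fit, limma's array weights, a minimum fold change of 1.5, and leaving out each library. A correction of each library for gene GC content and length, available for 15042 of the tested genes, and the removal of 2 libraries that stood apart were chosen after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9. Transcript isoforms and splicing were not analysed here, since the table has 1 value per gene.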

Results

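The transcriptome of Huh7 cells was sequenced in 12 libraries, 3 each from cells given solvent, disulfiram, thalidomide or both drugs. The groups allow each drug and the combination to be set against control, and ask whether the combination differs from either drug alone. TPM values below are means ± SD and log2 fold changes on log2(TPM + 1) are means ± SE, with 3 libraries per group. The depth of the libraries is unknown. Between 13693 and 15038 genes per library had a TPM of at least 1, and transcripts of the mitochondrial genome's protein-coding genes took 8.24% to 11.1% of the TPM total. Nothing states that replicates are separate cultures, so p-values measure only the spread between these libraries.

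The first principal component held 40.6% of the variance and had the disulfiram and combination libraries at scores from -0.4 to 45.3 and the control and thalidomide libraries from -37.3 to -16.1. The second disulfiram and the second combination library stood apart from the others of their groups. In both, a gene's deviation from its group mean followed its GC content across genes (Spearman's rho 0.61 and 0.67), against -0.17 to 0.12 in the controls and -0.59 to 0.48 in the other treated libraries. Genes are not independent replicates, so no p-value is given for these values. The difference between combination and control also followed GC content across genes (rho -0.44), whereas that between disulfiram and control did not (rho 0.01). Markers of other cell types were mostly near 0, with 5 of 20 immune, 3 of 14 endothelial and 7 of 14 fibroblast and stellate markers at a mean TPM of at least 1 in any group.

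**Figure D1:**
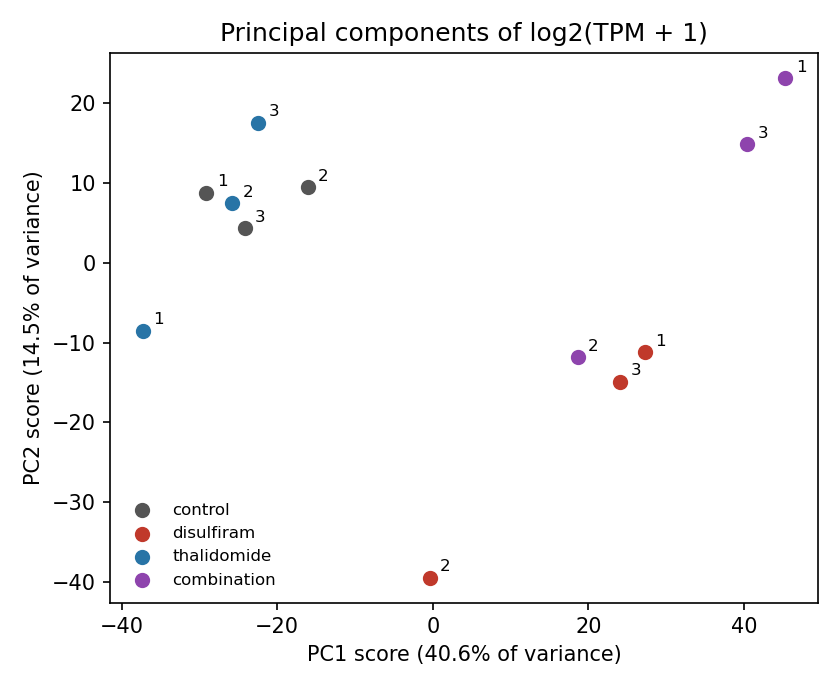
Scores of the 12 libraries on the first 2 principal components of log2(TPM + 1), 1 point per library, colored by group and numbered by replicate, with the share of variance on each axis. Disulfiram and combination libraries lie to the right of control and thalidomide libraries, with disulfiram 2 (-0.4) and combination 2 (18.6) lowest on PC1 in their groups.

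Disulfiram changed metal-binding, stress, lipid, immune and hepatocyte genes of Huh7 cells. Metallothioneins, which bind zinc and copper, and several heat shock genes rose most. MT1B, listed at 0 in the 3 control libraries, was at 155, 182 and 134 TPM with disulfiram. CRYAB, a small heat shock protein, rose from 2.14 ± 0.706 to 249 ± 105 TPM (log2 fold change 6.25 ± 0.26, adjusted p = 1.03e-07). HSPA6, a strictly inducible HSP70, rose from 0.103 ± 0.0306 to 48.8 ± 8.41 TPM (5.48 ± 0.18, adjusted p = 9.34e-09). HAMP, which encodes the iron hormone hepcidin, had the largest fall, from 80.6 ± 58.2 to 12 ± 2.58 TPM (-2.42 ± 0.43, adjusted p = 0.00396). In hg38 coordinates MT1B lies on chromosome 16 at 56651899 to 56653204, CRYAB on 11 at 111908565 to 111923722, and HSPA6 on 1 at 161524540 to 161526910. HAMP lies on 19 at 35280716 to 35285143, and each is an annotated gene. The netrin receptor gene UNC5B fell by 1.93 ± 0.23 and the transcription factor gene MYCN by 1.82 ± 0.17 on the log2 scale (adjusted p = 0.00044 and 8.68e-05). The signal recognition particle RNAs RN7SL2 (-1.96 ± 0.29) and RN7SL3 (-1.68 ± 0.33) fell and the histone gene HIST2H2AA4 rose (3.42 ± 0.77, adjusted p = 0.0131). Copies of these genes are near identical, so their reads cannot be assigned with certainty. RN7SL2 was at 1465, 836 and 2226 TPM in the controls and 259, 410 and 432 TPM with disulfiram. How far the unknown library preparation shaped the values of these RNAs was not tested. HIST2H2AA4 was at 0, 19.33 and 5.05 TPM in the controls, and its log2 fold change was 2.26 without control 1 and 4.44 without control 2. It was not past the threshold with only the compared groups in the fit.

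In all, 2034 of 15352 genes passed the threshold with disulfiram, 1340 higher and 694 lower, of which 251 and 63 changed at least 2-fold. The median of all genes shifted by 0.09 with disulfiram and by 0.20 with the combination, and median-of-ratios scaling, which removes such a shift, turned the balance to 768 higher and 969 lower. The count was 1227 without control 1, 1313 without control 3, 1293 without disulfiram 1 and 1170 without disulfiram 3. It was 2542 without the second disulfiram and second combination libraries, a removal chosen after seeing the data. Of 39 gene lists, camera placed 7 higher and 13 lower than other genes at the preset correlation and 0 past the threshold with an estimated one, and fry called 18.

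Of the 10 tested genes of the metallothionein and zinc export list, 6 rose and 0 fell with disulfiram (7 and 0 adjusted over the list alone). MT1M rose from 2.31 ± 0.563 to 135 ± 39.5 TPM (5.34 ± 0.31), MT1G from 41.9 ± 9.97 to 764.5 ± 255 TPM (4.14 ± 0.26) and MT2A from 354 ± 60 to 1236 ± 505 TPM (1.74 ± 0.26). These genes are paralogs in a cluster on chromosome 16 with similar sequences, so reads may be shared among them. The list was higher than other genes (median log2 fold change 1.31, camera adjusted p = 5.87e-07; adjusted p = 0.166 with an estimated correlation). That median includes fitted values of MT1B and MT1H, both listed at 0 in all controls, which depend on the pseudocount. Of 20 heat shock genes, 5 rose and 2 fell (5 and 4 adjusted over the list alone). Among them HSPA1A rose from 100.5 ± 17.3 to 250.2 ± 40.3 TPM (1.31 ± 0.23), with a near-identical copy in HSPA1B (0.98 ± 0.17), and the HSP70 co-chaperone BAG3 rose (0.64 ± 0.11). As a list the heat shock genes were not past the threshold (median 0.06, mean 0.42, adjusted p = 0.974).

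Lipid synthesis genes fell with disulfiram. Of 24 cholesterol synthesis and uptake genes, 18 fell and 0 rose (18 and 0 adjusted over the list alone). FDPS was at 1039 ± 165 and 548 ± 36.2 TPM (-0.91 ± 0.10), DHCR7 at 229.6 ± 38.2 and 117 ± 15.9 TPM (-0.96 ± 0.14). INSIG1, which holds the sterol sensor in the endoplasmic reticulum, fell by 1.04 ± 0.18 on the log2 scale. The list's median was -0.56 (adjusted p = 2.68e-17; adjusted p = 0.0603 with an estimated correlation). Of 20 fatty acid and triglyceride genes, 11 fell and 1 rose, the same numbers as adjusted over the list alone. FASN, the fatty acid synthase, fell from 252 ± 53.1 to 89.9 ± 16.8 TPM (-1.47 ± 0.18). The desaturase gene SCD fell from 705 ± 154 to 304 ± 59.2 TPM (-1.21 ± 0.17) and FADS2 from 364 ± 101 to 128 ± 29.6 TPM. The median was -0.57 (adjusted p = 3.03e-09; adjusted p = 0.0603 with an estimated correlation).

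Targets of ATF4, the transcription factor of the integrated stress response, moved both ways with disulfiram, 14 of 24 falling and 4 rising (15 and 6 adjusted over the list alone). The falls included serine synthesis genes, PHGDH from 306 ± 8.6 to 110 ± 9.9 TPM (-1.47 ± 0.11, adjusted p = 1.27e-05) and PSAT1 (-1.51 ± 0.12). Falls were also found for the amino acid transporter gene SLC7A5 (-1.35 ± 0.16) and the glutathione-degrading CHAC1 (-1.63 ± 0.31). The median was -0.61 (adjusted p = 5.87e-07; adjusted p = 0.158 with an estimated correlation). Of 22 genes of the unfolded protein response of the endoplasmic reticulum, 12 fell and 0 rose (14 and 0 adjusted over the list alone). The disulfide isomerase PDIA4 was at -1.15 ± 0.11 and the chaperones HSP90B1 at -0.98 ± 0.20 and HYOU1 at -0.90 ± 0.14. That list's median was -0.41 (adjusted p = 3.48e-10; adjusted p = 0.0603 with an estimated correlation).

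Some interferon, antigen presentation and NF-kB genes rose with disulfiram. Of 22 interferon response genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone). The GTPase gene GBP1 rose from 2.54 ± 0.808 to 17.0 ± 5.4 TPM (2.32 ± 0.26), and IRF9 (1.78 ± 0.14) and the antiviral OAS1 (1.33 ± 0.24) rose as well. The list median was 0.63 (adjusted p = 6.74e-09; adjusted p = 0.118 with an estimated correlation). Of 15 genes of MHC class I presentation, 11 rose and 1 fell (12 and 1 adjusted over the list alone). The peptide transporter gene TAP1 rose (0.93 ± 0.11). The list's median was 0.81 (adjusted p = 5.24e-06; adjusted p = 0.0603 with an estimated correlation). Of 23 NF-kB and cytokine genes, 8 rose and 1 fell (13 and 1 adjusted over the list alone), with TNFAIP3, a feedback inhibitor of NF-kB, at 1.37 ± 0.13 and NFKB2 at 0.83 ± 0.10. The median was 0.41 (adjusted p = 0.00016; adjusted p = 0.231 with an estimated correlation). Of 21 immediate early and MAPK feedback genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone), with FOSB at 2.02 ± 0.19 and DUSP5 at 1.47 ± 0.25. That list was not past the threshold (adjusted p = 0.0796). Its adjusted p was 0.01 without control 2, 0.0433 without control 3, 0.0481 without disulfiram 1 and 0.0384 without disulfiram 3. It was 0.0344 with median-of-ratios scaling, 0.0162 with quantile normalization and 0.0078 with no filter.

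Of 29 glycolysis and hypoxia genes, 12 rose and 0 fell with disulfiram (18 and 2 adjusted over the list alone). The glucose transporter gene SLC2A1 rose from 37.0 ± 10 to 96.4 ± 17.9 TPM (1.38 ± 0.21) and the vasodilator peptide gene ADM (1.27 ± 0.15). The median was 0.58 (adjusted p = 8.56e-06; adjusted p = 0.367 with an estimated correlation). Of 21 apoptosis regulators, 7 rose and 1 fell (10 and 1 adjusted over the list alone), with the pro-apoptotic BIK at 1.47 ± 0.19, BCL2L11 at 0.88 ± 0.14 and BBC3 at 0.71 ± 0.15. The list passed (adjusted p = 0.00247, and adjusted p = 0.0603 with an estimated correlation). Of 28 autophagy and lysosome genes, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with the lysosomal enzyme gene CTSB at 0.62 ± 0.09. That list passed as well (adjusted p = 0.00095, and adjusted p = 0.0603 with an estimated correlation).

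Some hepatocyte and replication genes fell with disulfiram, and most of those listed were not past the threshold. Of 23 proteins secreted by hepatocytes, 8 fell and 0 rose (10 and 0 adjusted over the list alone), with the apolipoprotein gene APOB from 34.6 ± 4.04 to 10.2 ± 1.35 TPM (-1.67 ± 0.29) and ITIH2 at -1.29 ± 0.25. The median was -0.59 (adjusted p = 5.02e-10; adjusted p = 0.189 with an estimated correlation). Albumin (ALB) was at 1277 ± 215 and 826 ± 208 TPM (-0.65 ± 0.23, adjusted p = 0.0867). AFP, the fetal liver protein made by many hepatocellular carcinomas, was at 240 ± 69 and 134 ± 31.3 TPM (-0.82 ± 0.37, adjusted p = 0.169). Neither passed the threshold, although ALB was past it with median-of-ratios scaling or the GC correction. Of 16 hepatocyte transcription factors, FOXA1 (-0.90 ± 0.10) and CEBPA (-0.84 ± 0.12) fell. The list was not past the threshold (adjusted p = 0.132), its median of 0.02 and mean of -0.04 differing in sign. Of 30 DNA replication and S phase genes, 9 fell and 0 rose (16 and 0 adjusted over the list alone), including the replicative helicase genes MCM5 (-0.80 ± 0.10), MCM6 (-0.74 ± 0.14) and MCM7 (-0.61 ± 0.09). The median was -0.29 (adjusted p = 2.98e-11; adjusted p = 0.158 with an estimated correlation).

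Among genes of the known targets of disulfiram, ALDH2 fell and NPLOC4 was not past the threshold. Of 15 aldehyde dehydrogenases, 3 fell and 0 rose with disulfiram (4 and 0 adjusted over the list alone), with a list median of -0.22 (adjusted p = 0.000225; adjusted p = 0.0603 with an estimated correlation). ALDH2, the mitochondrial enzyme that clears acetaldehyde (chromosome 12, 111766887 to 111817529), fell with disulfiram from 47.0 ± 1.22 to 29.5 ± 0.977 TPM (-0.66 ± 0.09, adjusted p = 0.00113). ALDH7A1 fell from 57.4 ± 6.2 to 39.4 ± 1.21 TPM (-0.53 ± 0.10). ALDH1A1 was at 584 ± 94.2 and 390 ± 88.9 TPM (-0.60 ± 0.19, adjusted p = 0.0541). It passed the threshold without control 1 (adjusted p = 0.0479) or disulfiram 1 (0.0355), with the GC correction, median-of-ratios scaling or array weights, or with a mean TPM of at least 5. NPLOC4 was at 69.2 ± 3.78 and 62.9 ± 3.92 TPM (-0.14 ± 0.09, adjusted p = 0.364). Of 33 proteasome and p97 pathway genes, 1 rose, UFD1 at 0.41 ± 0.12 (adjusted p = 0.0487), and 0 were past the threshold adjusted over the list alone. UFD1 missed the threshold without any 1 of control 1, 2 or 3 or disulfiram 1, 2 or 3, its adjusted p then being 0.0695 to 0.137. It also missed it with median-of-ratios scaling (0.181), no filter (0.109), the GC correction (0.0551) or the second disulfiram and combination libraries removed (0.0623). The list was not past the threshold (adjusted p = 0.569), except with quantile normalization. Of 25 copper transport and lipoylation genes, 1 rose, the superoxide dismutase chaperone CCS at 0.38 ± 0.07, and 2 fell, including the copper exporter ATP7B at -0.60 ± 0.12 (list adjusted p = 0.58). CCS was not past the threshold with median-of-ratios scaling. Of 25 NRF2 targets, 3 rose and 3 fell (4 and 5 adjusted over the list alone), with EPHX1 at 0.84 ± 0.09, NQO1 at -0.69 ± 0.11 and PGD at -0.75 ± 0.08. The list was not past the threshold (adjusted p = 0.206), except without control 1 (median -0.09, adjusted p = 0.0182).

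**Figure D2:**
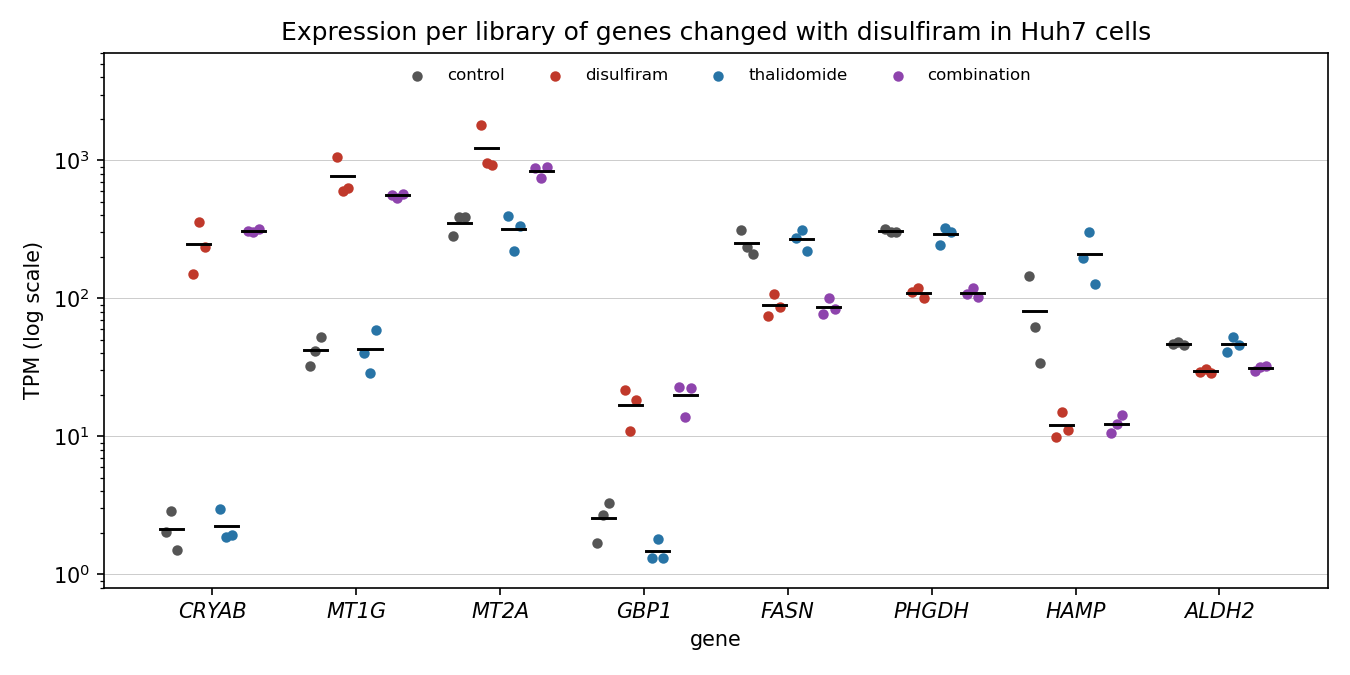
TPM on a log scale of 8 genes in the 12 libraries, 3 points per group, with black bars at the group means. CRYAB rises from a mean of 2.14 in control to 249 with disulfiram and 308 with the combination, while FASN falls from 252 to 89.9 and 87.1.

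Thalidomide alone changed no gene past the threshold, the gene of its target included. CRBN, which encodes cereblon (chromosome 3, 3144628 to 3179727), was at 10.8 ± 1.43 TPM in control and 12.1 ± 1.06 TPM with thalidomide (0.16 ± 0.24, adjusted p = 0.988). Limma called 0 of 15352 genes, with 873 at an unadjusted p below 0.05 against 768 expected by chance. The smallest adjusted p was 0.0676, for the basement membrane gene NID2 (102.7 ± 11.1 and 63.3 ± 2.93 TPM, -0.69 ± 0.09), which was chosen after its values were seen. NID2 was past the threshold without control 1 (adjusted p = 0.0154), with the GC correction (0.0473) and with a mean TPM of at least 5 (0.0457). Leaving out control 1 gave 25 genes, control 2 1, control 3 2 and thalidomide 1 1, and fits of the compared groups alone gave 3. ALDH2 (-0.02 ± 0.09, adjusted p = 0.995) and AFP (240 ± 69 and 379 ± 155 TPM, 0.61 ± 0.37, adjusted p = 0.937) were not past the threshold either.

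Some lists shifted with thalidomide as sets, without a single member past the threshold over all genes. The ATF4 list had a median of -0.32 (adjusted p = 4.92e-12; adjusted p = 0.192 with an estimated correlation), and 4 of its 24 members were lower and 0 higher adjusted over the list alone. ATF4 itself was at 504 ± 59.2 and 411 ± 54.5 TPM (-0.30 ± 0.11, adjusted p = 0.815). In the 3 disulfiram libraries ATF4 was at 314, 346 and 285 TPM. CHAC1, a member picked here after its values were seen, was at 22.4 ± 10.3 TPM in control and 7.70 ± 1.21 TPM with thalidomide (-1.31 ± 0.31, adjusted p = 0.504). Proteins secreted by hepatocytes had a median of 0.17 (adjusted p = 1.47e-06; adjusted p = 0.635 with an estimated correlation), with the apolipoprotein gene APOA2 at 1852 ± 264 and 2346 ± 133 TPM (0.35 ± 0.10, adjusted p = 0.689). Immediate early genes had a median of -0.20 (adjusted p = 7.11e-05; adjusted p = 0.29 with an estimated correlation), with DUSP1 at 156 ± 27.4 and 134 ± 16.7 TPM and 1 of 21 members lower adjusted over the list alone. Heat shock genes had a median of -0.20 (adjusted p = 0.000114; adjusted p = 0.66 with an estimated correlation), with HSP90AB1 at 845 ± 27 and 742 ± 29 TPM. They were not past the threshold without thalidomide 2 (adjusted p = 0.265). The 20 tested genes of the cereblon ligase and its drug-induced substrates were not past the threshold (median -0.04, mean 0.02, adjusted p = 0.799), with 1 higher and 0 lower adjusted over the list alone. In all, 11 of 39 lists passed with camera and 0 with the estimated correlation or with fry, and 5 of the 10 ways to split these 6 libraries gave as many or more lists.

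With the combination, the lists of metallothionein, interferon and MHC class I genes were higher than other genes by camera at the preset correlation (adjusted p = 0.247, 0.224 and 0.224 with an estimated one). Those of cholesterol and fatty acid synthesis, the unfolded protein response and hepatocyte secretion were lower (adjusted p = 0.157, 0.14, 0.157 and 0.224 with an estimated one). MT1B was at 194, 143 and 171 TPM, CRYAB at 308 ± 9.46 TPM (6.65 ± 0.26, adjusted p = 5.05e-08) and HSPA6 at 62.5 TPM (5.81 ± 0.18, adjusted p = 4.72e-09). MT1M rose by 4.97 ± 0.31 and MT1G by 3.73 ± 0.26 on the log2 scale. Among the largest falls were HAMP (12.3 TPM, -2.37 ± 0.43, adjusted p = 0.00409), UNC5B (-1.97 ± 0.23) and CHAC1 (-1.66 ± 0.31). The carbonic anhydrase gene CA4 fell from 71.9 ± 33.1 to 15.3 TPM (-2.09 ± 0.35, adjusted p = 0.003). DDC, the aromatic amino acid decarboxylase, fell from 21.8 ± 1.18 to 5.88 TPM (-1.73 ± 0.15, adjusted p = 6.23e-05). The small nucleolar RNA SNORD3A rose (9.84 ± 11.7 to 73.3 TPM, 3.60 ± 0.97, adjusted p = 0.0218), but not past the threshold without control 1 (2.40, adjusted p = 0.0676), combination 1 (0.0519) or combination 3 (0.0784), or without the filter on low values. Its controls were at 0.11, 22.8 and 6.61 TPM, and without control 2 its log2 fold change was 4.61. With disulfiram alone SNORD3A was at 53.5 TPM (3.22 ± 0.97, adjusted p = 0.0482). It was not past the threshold between the combination and disulfiram (adjusted p = 0.851).

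A total of 3852 genes passed the threshold with the combination, 2823 higher and 1029 lower, with 334 and 81 changed at least 2-fold. Median-of-ratios scaling turned the balance to 1351 higher and 1877 lower. The count was 1970 without control 1, 2093 without control 3, 1675 without combination 1, 1429 without combination 3, and 5846 without the second disulfiram and combination libraries. Of 39 lists, camera placed 4 higher and 13 lower at the preset correlation and 0 past the threshold with an estimated one, and fry called 22. Of the gene calls, 1359 higher and 57 lower were in the third of genes with the lowest GC content, and 543 higher and 624 lower in the third with the highest.

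Cholesterol genes fell with the combination, 14 of 24 with 0 rising (15 and 0 adjusted over the list alone), including DHCR7 (-1.08 ± 0.14). The list's median was -0.57 (adjusted p = 1.23e-13; adjusted p = 0.157 with an estimated correlation). Of 20 fatty acid genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), with FASN at 87.1 ± 11.9 TPM (-1.51 ± 0.18) and SCD at 303.5 ± 27.2 TPM (-1.20 ± 0.17). That list had an adjusted p of 2.72e-08 (adjusted p = 0.14 with an estimated correlation). In the ATF4 list 14 genes fell and 3 rose, with PHGDH at 109.5 ± 7.98 TPM (-1.48 ± 0.11) and the stress factor ATF3 rising from 17.5 to 44.5 ± 7.92 TPM (1.29 ± 0.18). The ATF4 list had a median of -0.62 (adjusted p = 2.73e-09, and adjusted p = 0.157 with an estimated correlation). Of 22 unfolded protein response genes 11 fell, including PDIA4 (-1.23 ± 0.11) and the chaperone CALR from 1307 to 857 ± 37.3 TPM (-0.61 ± 0.11). Their list's adjusted p was 1.18e-06 (adjusted p = 0.157 with an estimated correlation). Of 23 secreted hepatocyte proteins 9 fell, among them complement C3 from 1284 to 633 ± 52.7 TPM (-1.01 ± 0.14) and the thyroxine carrier TTR (-0.99 ± 0.21). The secreted proteins had an adjusted p of 5.93e-09 (adjusted p = 0.224 with an estimated correlation). Of 16 hepatocyte transcription factors 5 fell, including CEBPA (-1.07 ± 0.12) and FOXA1 (-0.67 ± 0.10). The list passed (adjusted p = 0.00642, and adjusted p = 0.224 with an estimated correlation), a call lost with the GC correction (median 0.08, adjusted p = 0.0601). Of 30 replication genes 11 fell and 0 rose (12 and 1 adjusted over the list alone), with MCM5 (-0.82 ± 0.10) and MCM7 (-0.65 ± 0.09). Their list's adjusted p was 2.05e-08 (adjusted p = 0.224 with an estimated correlation).

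With the combination 6 of 10 metallothionein and zinc export genes rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 1.15 (adjusted p = 0.000125, and adjusted p = 0.247 with an estimated correlation). Of 22 interferon response genes 15 rose and 0 fell (19 and 0 adjusted over the list alone), with GBP1 at 2.55 ± 0.26 and IRF9 at 1.38 ± 0.14. Their median was 0.65 (adjusted p = 3.75e-06, and adjusted p = 0.224 with an estimated correlation). Of 15 MHC class I genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), including B2M from 633.5 to 1182 ± 209 TPM (0.89 ± 0.13). The list passed (adjusted p = 0.0051, and adjusted p = 0.224 with an estimated correlation), but not without the second disulfiram and combination libraries (adjusted p = 0.0604). Of 21 apoptosis regulators 12 rose and 1 fell (14 and 2 adjusted over the list alone), including PMAIP1 (1.20 ± 0.27) and BIK (0.99 ± 0.19). The list passed at an adjusted p of 0.0431 (adjusted p = 0.224 with an estimated correlation). It did not pass with median-of-ratios scaling (0.0528), only the compared groups (0.06) or array weights (0.0723), nor without combination 2 (0.104). Of 20 heat shock genes 6 rose and 2 fell (9 and 2 adjusted over the list alone), with HSPA1A at 288 ± 55.9 TPM (list adjusted p = 0.707).

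CRBN was at 21.4 ± 5.64 TPM with the combination and 10.8 ± 1.43 TPM in control (0.90 ± 0.24, adjusted p = 0.0207). Single libraries were at 12.2, 10.7 and 9.37 TPM in control and 26.5, 15.3 and 22.2 TPM with the combination. The call was lost without control 3 (adjusted p = 0.0689), combination 1 (0.088) or combination 3 (0.0724) and without the filter on low values. With disulfiram alone CRBN was at 15.4 ± 5.47 TPM (0.43 ± 0.24, adjusted p = 0.271), past the threshold without disulfiram 2 (0.0461) or both second libraries (0.0149) and with array weights (0.0334). The combination was not past the threshold against disulfiram for CRBN (0.47 ± 0.24, adjusted p = 0.321). ZNF692, a zinc finger gene in the list of cereblon substrates, was at 20.8 ± 3.62 TPM in control, 24.4 ± 1.64 with disulfiram, 40.4 ± 6.58 with thalidomide (0.93 ± 0.14, adjusted p = 0.179). It was at 33.6 ± 2.46 TPM with the combination, where it passed the threshold (0.68 ± 0.14, adjusted p = 0.00695). Of 20 genes of that list 4 rose and 0 fell, and the list was not past the threshold (adjusted p = 0.26). Of 33 proteasome and p97 pathway genes 12 rose and 0 fell (14 and 2 adjusted over the list alone). The ATPase subunit gene PSMC1 rose from 100.9 to 162 ± 25.1 TPM (0.68 ± 0.16, adjusted p = 0.0123) and PSMC2 from 67.9 to 113 ± 26.8 TPM (0.70 ± 0.19, adjusted p = 0.0201). Without control 1 or combination 3 neither was past the threshold (PSMC1 0.0501 and 0.0563, PSMC2 0.0612 and 0.0821), nor was PSMC2 without combination 1 (0.0846). The proteasome and p97 pathway list had an adjusted p of 0.112, and was past the threshold with quantile normalization (2.3e-05), no filter (0.0218), array weights (0.0264) and without control 3 (0.0334).

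Of 13 mRNAs of the mitochondrial genome, 4 fell and 0 rose with the combination, with MT-ND3, a subunit of respiratory complex I, from 6624 to 4476 ± 815 TPM (-0.58 ± 0.11, adjusted p = 0.00501). The other 3 calls were each lost without combination 1 or 3 (adjusted p from 0.062 to 0.125) and with no filter. They were also lost without control 3 for MT-ATP8 (0.0593), control 1 for MT-CO3 (0.0735) and control 2 (0.0684) or 3 (0.104) for MT-ATP6. The median was -0.16 (adjusted p = 2.95e-05; adjusted p = 0.308 with an estimated correlation), and with quantile normalization the mitochondrially encoded mRNAs were not past the threshold (adjusted p = 0.111). Of 30 G2/M and mitosis genes 2 rose and 5 fell (4 and 6 adjusted over the list alone), with falls in CDC20, an activator of the anaphase-promoting complex (-0.62 ± 0.12), and the ubiquitin-conjugating enzyme gene UBE2C (-0.45 ± 0.08). The kinase gene BUB1 was at 22.2 and 35.9 ± 6.74 TPM (0.65 ± 0.18, adjusted p = 0.0256), a call lost without control 1, control 3, combination 1 or combination 3 (adjusted p from 0.0693 to 0.101). The list's median of 0.27 and its camera direction, which was downward, differed in sign (adjusted p = 0.266), and with the GC correction the G2/M and mitosis list was past the threshold (median 0.03, adjusted p = 0.0294). ALDH2 (31.2 ± 1.37 TPM, -0.58 ± 0.09, adjusted p = 0.00234) and 3 other aldehyde dehydrogenases of 15 fell (list adjusted p = 0.000545, and adjusted p = 0.14 with an estimated correlation). Those 3 calls depend on single libraries. ALDH1B1 was not past the threshold without control 3 or combination 1 or 3 (adjusted p from 0.062 to 0.0724), nor ALDH18A1 without control 1 or 2 or combination 1 or 3 (0.052 to 0.0852). ALDH7A1 was not without control 1 or 2 or combination 2 or 3 (0.0608 to 0.105), nor with no filter, only the compared groups or both second libraries removed (0.0518 to 0.0614). ALDH1A1 (536 TPM, -0.13 ± 0.19, adjusted p = 0.623), and NPLOC4 (57.7 TPM, -0.26 ± 0.09, adjusted p = 0.0537) were not past the threshold. Nor were AFP (-0.52 ± 0.37, adjusted p = 0.295) and ALB (-0.32 ± 0.23, adjusted p = 0.297). NPLOC4 was past it without combination 2 (adjusted p = 0.0367) and with median-of-ratios scaling, quantile normalization, array weights or a mean TPM of at least 5, and ALB with the GC correction (-0.58, adjusted p = 0.0167).

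**Figure D3:**
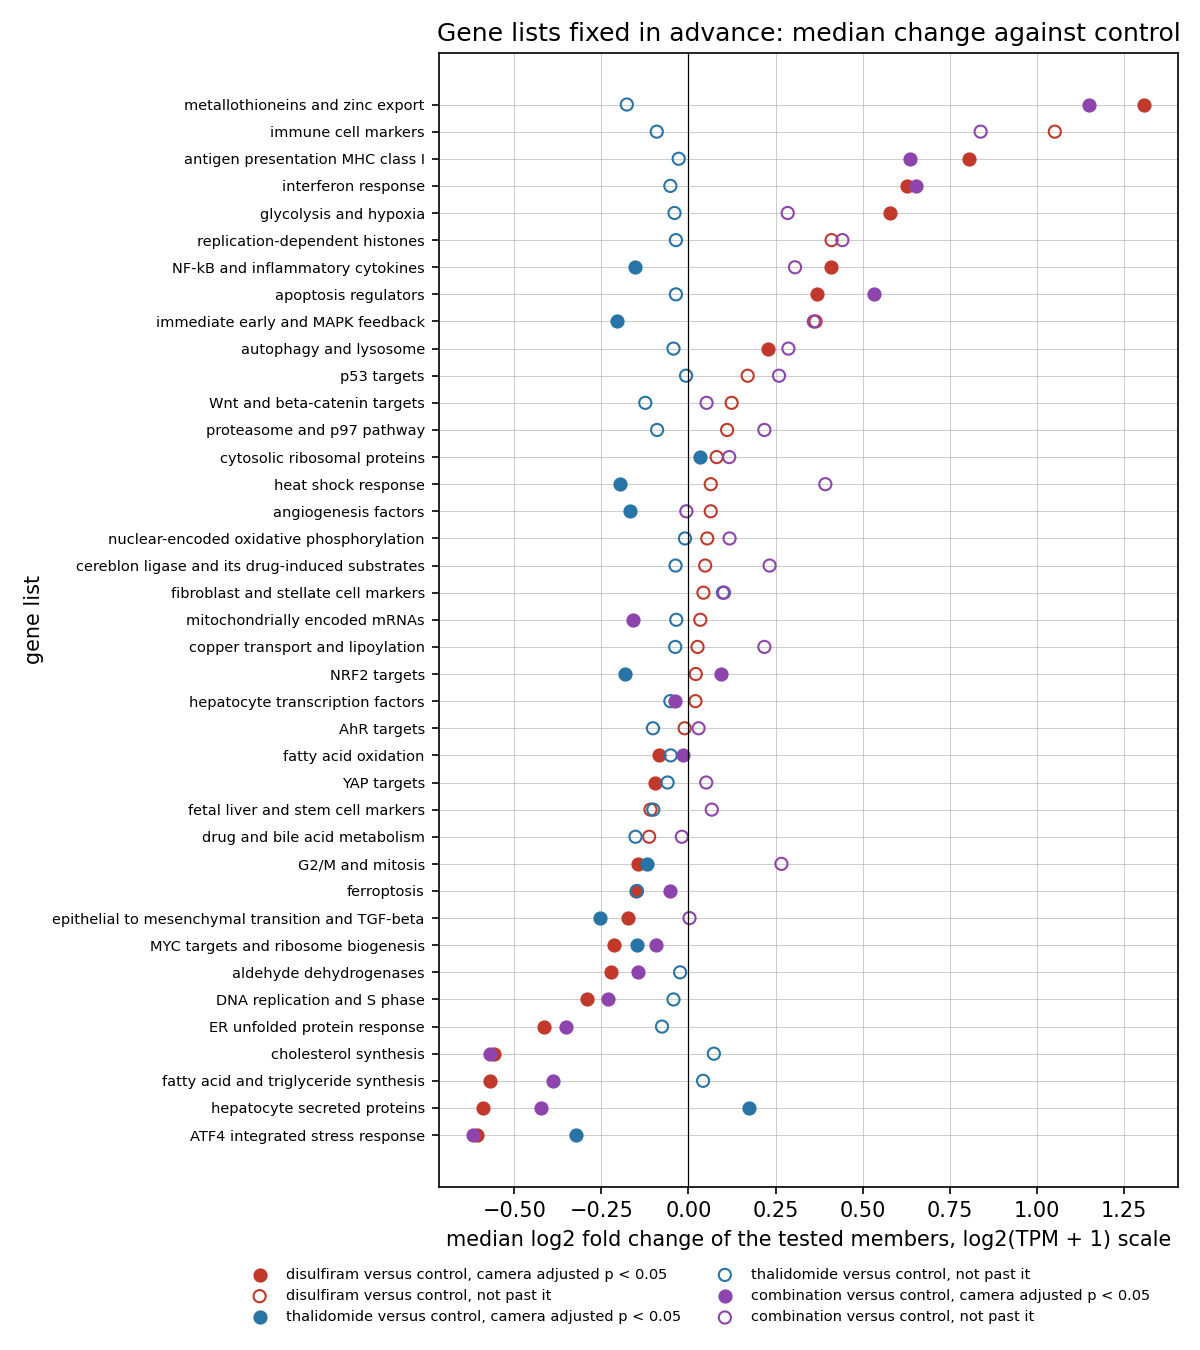
Median log2 fold change against control of the tested members of each of 39 gene lists for disulfiram, thalidomide and the combination, with filled points where camera's adjusted p at the preset correlation was below 0.05. Metallothioneins lie furthest right for disulfiram (1.31) and the combination (1.15), and the cholesterol genes lie left of zero for both (-0.56 and -0.57).

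Between the combination and disulfiram alone, 1 of 15352 genes passed the threshold. RDM1, a RAD52-like gene (chromosome 17, 35918066 to 35930773), was at 7.72 ± 0.487 TPM with disulfiram and 2.99 ± 0.17 with the combination (-1.13 ± 0.12, adjusted p = 0.0135). It was at 4.84 ± 0.262 TPM in control and 6.05 ± 0.887 TPM with thalidomide. RDM1 was lower in 3 of 3 combination libraries, but not past the threshold without disulfiram 1 (0.148), disulfiram 3 (0.082), combination 1 (0.117) or combination 3 (0.139). Nor was it with only the compared groups (0.113), a mean TPM of at least 5 (0.0563) or both second libraries removed (0.0577). Limma placed 2631 genes at an unadjusted p below 0.05 against 768 expected, and gave 36 genes without combination 2, 2 without disulfiram 2 and 2902 with array weights. The difference followed GC content across genes (rho -0.64). As lists, G2/M and mitosis genes were higher (median 0.40, adjusted p = 0.0218) and mitochondrial mRNAs (-0.18, adjusted p = 6.3e-06) and glycolysis and hypoxia genes (-0.21, adjusted p = 6.3e-06) lower. NF-kB and cytokine genes (-0.11, adjusted p = 0.00163) and MHC class I genes (-0.20, adjusted p = 0.0363) were lower as well. Each had an adjusted p = 0.837 with an estimated correlation and 0 members past the threshold over all genes, and fry called 0 lists. The abundant mitotic genes PTTG1 (0.06 ± 0.08) and UBE2C (-0.04 ± 0.08) were not past the threshold. The G2/M and mitosis call was lost with the GC correction (adjusted p = 0.189), without disulfiram 2 (0.0674), combination 1 (0.0561) or combination 3 (0.0621). The mitochondrial call was lost with quantile normalization (0.139), and the NF-kB call without combination 2 (0.0915) or both second libraries (0.0524). The MHC class I call was lost without disulfiram 1 (0.11), combination 2 (0.106) or combination 3 (0.0909). It was also lost with either scaling, no filter, the GC correction or the removal of both second libraries (0.0524 to 0.131).

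The interaction asked whether the combination departed from the sum of the single-drug changes. Limma called 0 of 15352 genes, with 1580 at an unadjusted p below 0.05 against 768 expected, and the smallest adjusted p was 0.0554, for RDM1 (-1.39 ± 0.17). Leaving out control 3 gave 1 gene. The interaction followed GC content across genes (rho -0.63).

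Between the combination and thalidomide alone, 4946 genes passed the threshold, 3834 higher and 1112 lower. MT1B, CRYAB (6.59 ± 0.26), HSPA6 (5.77 ± 0.18) and MT1M (5.34 ± 0.31) had the largest rises. HAMP fell from 209 ± 89.4 to 12.3 TPM (-3.90 ± 0.43, adjusted p = 0.000195) and UNC5B by 2.43 ± 0.23 on the log2 scale. The small nucleolar RNA SNORA57, listed at 0 in all controls, was at 17.1 ± 9.29 TPM with thalidomide and 2.87 TPM with the combination (-2.97 ± 1.06, adjusted p = 0.0495). It was not past the threshold without any 1 of thalidomide 1, 2 or 3 or combination 1 or 3 (adjusted p from 0.0656 to 0.165), nor with a pseudocount of 0.1 (0.0599), no filter (0.13) or the GC correction (0.0637). Without combination 2 the log2 fold change was -4.06. The median of all genes shifted by 0.22, and median-of-ratios scaling gave 1811 higher and 2255 lower. The count was 2407 without thalidomide 1, 2278 without combination 1 and 2171 without combination 3. Between disulfiram and thalidomide 2624 genes passed, 1826 higher and 798 lower with disulfiram, with 1695 without disulfiram 1 and 1593 without disulfiram 3. Median-of-ratios scaling turned that balance to 1030 higher and 1240 lower, and quantile normalization gave 1148 and 1164.

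The changes with disulfiram and with the combination against control shared 964 higher and 539 lower genes, 71.9% and 77.7% of the disulfiram calls. Together these 1503 shared calls became 871 without control 1, 951 without control 3, 932 without disulfiram 3 and 909 without combination 3. Independent lists of these sizes would share 246 and 46.5, and 1 gene was called in opposite directions. Log2 fold changes correlated across genes (Pearson's r 0.740, Spearman's rho 0.684), although both comparisons use the same 3 controls. Among 100 simulated sets of unchanged groups with shared controls, the median r was 0.524 and the highest 0.915, and 21 sets reached the r of 0.740. The shared count was reached in 1 set for higher and in 1 set for lower genes. The covariance was 0.138, against a simulated median of 0.027 and a highest of 0.177. Simulated controls had the residual spread of all groups, and controls of that spread can give a correlation as high. Deviations in the real controls followed GC content less than in some treated libraries. How much the real shared controls add therefore cannot be told from this simulation. The comparison of disulfiram with control and that of the combination with thalidomide use separate libraries, and shared 968 higher and 500 lower genes, 72.2% and 72.0% of the disulfiram calls. Independent lists would share 335 and 50.3, and 2 genes were called in opposite directions. Log2 fold changes of these comparisons correlated across genes (Pearson's r 0.599, Spearman's rho 0.551). Both came from the same fit with 1 estimate of spread per gene, so calls can coincide more often than in independent lists.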

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

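The tests of GC content for the G2/M list and for the split with most genes were chosen only after the results were seen, whereas the counts of other splits of the libraries were planned. In the interaction of disulfiram and thalidomide, which tests whether the effect of thalidomide differed between cells with and without disulfiram, 6 gene lists passed camera's threshold at the preset correlation. G2/M and mitosis genes were above the sum of the single-drug changes (median 0.51, adjusted p = 0.00176), as were heat shock genes (median 0.36, adjusted p = 0.00752) and proteasome and p97 pathway genes (median 0.16, adjusted p = 0.0164). Glycolysis and hypoxia genes (median -0.15, adjusted p = 0.00176), mitochondrially encoded mRNAs (median -0.15, adjusted p = 0.00176) and proteins secreted by hepatocytes (median -0.25, adjusted p = 0.0038) were below it. No member of these lists passed the threshold alone, limma calling 0 genes with 1580 at an unadjusted p below 0.05, and each list had an adjusted p = 0.937 with an estimated correlation, while fry called 0 lists. Single libraries decide most of these calls. Without thalidomide 2 the adjusted p was 0.0675 for G2/M, 0.377 for heat shock, 0.89 for proteasome, 0.109 for glycolysis and 0.0501 for secreted proteins. Without control 3 it was 0.0689 for heat shock, 0.152 for proteasome, 0.152 for glycolysis and 0.0689 for secreted proteins. Without disulfiram 3 it was 0.141 for heat shock and 0.126 for proteasome genes, and without combination 3 it was 0.0834 for the latter. The mitochondrial list kept its call without any 1 library and lost it with quantile normalization (0.597). The call of the secreted proteins was lost with quantile normalization (0.0606) and without the second disulfiram and combination libraries (0.126), and that of the proteasome list with median-of-ratios scaling (0.229). Other lists passed in some alternatives. The ATF4 list (median 0.26, adjusted p = 0.0515) was past the threshold in 8 of them (0.000105 with the GC correction to 0.0499 without combination 3). MYC targets (median 0.20, adjusted p = 0.0836) were past it in 9 (0.000603 with the GC correction to 0.049 without combination 1). Immediate early genes (0.0124) and YAP targets (0.0209) passed with the GC correction too. Unfolded protein response genes passed with no filter (0.0166) and without control 2 (0.0343), among other alternatives. Not every list that passed in an alternative is named here.

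Other splits of the libraries, drawn within those with and within those without disulfiram, were counted. For lists, 60 of 100 splits gave at least the 6 of the real split, the highest other 19, so chance cannot be excluded. For genes the real count was 0, which 100 of 100 splits reach by construction, so that count decides nothing. The highest other split called 1069. That split set control 1 and thalidomide 1 and 2 against control 2 and 3 and thalidomide 3, and disulfiram 1 and combination 1 and 3 against disulfiram 2 and 3 and combination 2, and a count so far above the real one points to a structure of the samples. Deviations followed GC content in some libraries (rho -0.59 in combination 1, 0.67 in combination 2) and hardly in others (-0.17 to 0.12 in the controls, -0.06 in thalidomide 2). The interaction in that split followed GC content across genes (rho 0.66). After the GC correction (rho 0.03) it called 301 genes.

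For the G2/M and mitosis list, GC content bias was weighed against a joint effect of both drugs. Against control, camera also called that list with each drug alone at the preset correlation. The disulfiram call was lost without both second libraries (median -0.059, adjusted p = 0.0535). The thalidomide call was lost with quantile normalization (median -0.089, adjusted p = 0.0544) or the GC correction (-0.111, 0.0914), and without thalidomide 2 (-0.053, 0.807). The list's mean interaction was 0.47 ± 0.24 as deposited and 0.284 ± 0.144 after the correction for GC content and length, 1.98 and 1.97 standard errors from 0. The correction removed part of the mean and part of its spread, so the part that remains neither excludes GC bias nor shows a joint effect, and the cause cannot be told apart with these libraries. Quality of RNA, read depth and library preparation, which might also act through GC content, could not be tested since the files hold no reads.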

How the results depend on the processing

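The GC and length correction and the removal of the second disulfiram and combination libraries were chosen after the data were seen, and all other alternatives were planned. A gene result is 1 gene in 1 comparison and 1 setting, and genes chosen after their values were seen are included. Median-of-ratios scaling kept 199 gene results on their side of the threshold and left 11 weaker and 3 stronger. No filter left 33 weaker, and the fits without 1 library left 156 weaker, 6 stronger and 1116 as they were. Of 273 list results, a pseudocount of 0.1 changed 0. For each change below the cause was not tested, except that fits without a library have fewer samples and a minimum fold asks for more than a change. The unknown depth sets a limit on low genes, whose TPM has no counting error.

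Reversals were counted only where the main fit or the alternative passed the threshold. Camera's direction, which sets a list against other genes and need not share the sign of its median, reversed in 3 such results, all lists. With quantile normalization, the list nuclear-encoded oxidative phosphorylation in combination versus control had a median of 0.143, and the list cytosolic ribosomal proteins in combination versus thalidomide 0.106. Without thalidomide 3, the list glycolysis and hypoxia in thalidomide versus control had a median of 0.050, against -0.176 without control 3, the lowest with 1 library left out.

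For disulfiram against control (2034 genes), array weights gave 3882 and a minimum fold of 1.5 gave 58. For the combination against control (3852), these gave 8162 and 63, and the removal of disulfiram 2 and combination 2 gave 5846. For the combination against thalidomide (4946) they gave 7540 and 106. For disulfiram against thalidomide (2624), the minimum fold gave 134 and only the compared groups 1602. The shared calls of disulfiram and the combination (1503) were 3090 with array weights and 44 with the minimum fold. Array weights did not converge in every fit.

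For thalidomide (0), a mean TPM of at least 5, the GC correction and the removal of 2 libraries gave 1 each, and only the compared groups gave 3. For the combination against disulfiram (1), no filter gave 5, array weights 2902, and a mean TPM of at least 5, the replicate block, only the compared groups and the minimum fold 0 each. For the interaction (0), both scalings, the pseudocount, array weights, the GC correction and the removal of 2 libraries gave 1 each, and no filter 3.

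Leaving out 1 library gave 1170 to 1990 genes for disulfiram (1227 without control 1, 1313 without control 3, 1293 without disulfiram 1, 1170 without disulfiram 3), 0 to 25 for thalidomide (25 without control 1, 2 without control 3, 1 without control 2 or thalidomide 1) and 1429 to 5092 for the combination (1970 without control 1, 2093 without control 3, 1675 without combination 1, 1429 without combination 3). The combination against disulfiram gave 0 to 36 (36 without combination 2, 2 without disulfiram 2, 0 without disulfiram 1 or 3 or combination 1 or 3), the combination against thalidomide 2171 to 5842 (2407 without thalidomide 1, 2278 without combination 1, 2171 without combination 3), disulfiram against thalidomide 1593 to 2812 (1695 without disulfiram 1, 1593 without disulfiram 3) and the interaction 0 to 1 (1 without control 3). Lists called against control (48) numbered 46 to 54. The shared calls were 871 to 1640 (871 without control 1, 951 without control 3, 932 without disulfiram 3, 909 without combination 3).

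With the replicate block, disulfiram called 1786 genes, the combination 3584, the combination against disulfiram 0, the lists 51 and the shared calls 1315. RDM1 in combination versus disulfiram (adjusted p = 0.0547), SNORA57 in combination versus thalidomide (0.0749) and OSGIN1 in disulfiram versus control (0.0531) were not past the threshold with it. The block brought 4 list results past the threshold. Among them were the proteasome and p97 pathway list for the combination (0.0481) and thalidomide (0.0317) against control. Fetal liver and stem cell markers passed for the combination against control as well (0.0481). The replicate numbers were not taken to pair the libraries, since only 4 of 18 pairs with a shared number had a residual correlation over 0.1. As a hint from the data, 6 of 12 libraries matched their own number best, where chance gives 4. Disulfiram and combination libraries of numbers 1, 2 and 3 correlated at 0.21, 0.37 and 0.03, and their deviations followed GC content alike (rho -0.48 and -0.59, 0.61 and 0.67, -0.31 and -0.37). The 3 deviations of a group sum to 0 for each gene, so these are not 3 separate matches.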

Other observations

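The test of median-of-ratios scaling, the test for immune cells and the correlation of thalidomide's changes were chosen only after their result was seen, as were the genes named in the next 2 paragraphs. Disulfiram also changed matrix and p53 target genes that the comparisons above leave out. Of 21 genes of epithelial to mesenchymal transition and TGF-beta, 5 fell and 2 rose (5 and 2 adjusted over the list alone; list adjusted p = 0.0372, and adjusted p = 0.243 with an estimated correlation). That list's call was lost without control 2 (0.121) or disulfiram 1 (0.175) and with either scaling, the GC correction or either change of the filter (0.0578 to 0.27). Among its members CTGF, a secreted matrix-associated factor, fell from 258 to 108 TPM (-1.27 ± 0.20, adjusted p = 0.0021) and the collagen gene COL4A1 from 2.93 to 0.753 TPM (-1.17 ± 0.15). Of 21 p53 targets 6 rose and 0 fell (6 and 1 adjusted over the list alone), without a call for the list (adjusted p = 0.156). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 41.2 to 65.5 TPM (0.67 ± 0.20, adjusted p = 0.0419) and BTG2 by 0.62 ± 0.14 on the log2 scale. CDKN1A was not past the threshold without control 1 or 3 or disulfiram 1, 2 or 3 (adjusted p from 0.0728 to 0.137), nor with either scaling, no filter or both second libraries removed (0.0682 to 0.113). BTG2 was not past it without control 3 (0.0589).

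FGF19, a hormone of bile acid control, fell with disulfiram from 14.9 to 5.63 TPM (-1.24 ± 0.17, adjusted p = 0.000931). TIMP1, an inhibitor of matrix proteases, rose from 28.5 to 65.2 TPM (1.21 ± 0.20). ECI1, HADH and ETFB, enzymes of mitochondrial fatty acid oxidation, fell by 0.57 ± 0.11, 0.59 ± 0.11 and 0.44 ± 0.09 on the log2 scale. Of 24 fatty acid oxidation genes 3 fell and 1 rose (list adjusted p = 0.00592, and adjusted p = 0.318 with an estimated correlation). The hemoglobin gene HBA1, whose copy HBA2 is near identical, rose from 0.847 to 7.15 TPM with disulfiram (2.13 ± 0.17, adjusted p = 3.18e-05) and was at 8.22 TPM with the combination. S100A9, a calcium-binding protein gene, was at 1.72 TPM in control and 4.92 TPM with thalidomide (1.15 ± 0.22, adjusted p = 0.37), past the threshold only in the fit without control 1 (adjusted p = 0.0429).

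More genes were called higher than lower with the combination against control, 73.3% of 3852. After median-of-ratios scaling 41.9% were higher, but that scaling brings the median of all genes near 0 by its construction. The test therefore decides nothing, and whether abundant transcripts with a smaller share of the TPM total account for the balance stays open. GC content bias may account for it in part, since the share was 96.0% in the third of genes with the lowest GC content and 46.5% in the third with the highest. For disulfiram against control, which did not follow GC content across genes (rho 0.01), 65.9% of the calls were higher. An excess of higher calls was thus also present without such a trend. Correction for GC content and length left 76.7% of the combination's calls higher, but it returns each library to its own median and so says nothing of the shift of all genes. A rise of many transcripts by the drugs themselves stays open and was not tested, as no spike-in or count per cell is given.

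CD68, a lysosomal glycoprotein used as a macrophage marker, rose from 10.2 ± 4.55 to 67.6 ± 1.14 TPM with disulfiram (2.71 ± 0.27, adjusted p = 0.00013). LYZ rose from 5.34 to 12.2 TPM (1.05 ± 0.26) and CD3D from 7.17 to 14.8 TPM (1.06 ± 0.31). Those 2 calls were lost without control 1, control 2 or disulfiram 1 for LYZ (adjusted p from 0.0595 to 0.0777), and without control 1 or 3 or disulfiram 1, 2 or 3 for CD3D (0.0513 to 0.155). With no filter LYZ was not past the threshold either (0.0622). Nor was CD3D with either scaling, no filter, only the compared groups or both second libraries removed (0.067 to 0.11). Immune cells in the cultures would bring their other transcripts, but the 15 immune markers under 1 TPM in control rose together by 0.833 TPM, which is 1.45% of the rise of CD68 at 57.4 TPM. PTPRC, carried by all leukocytes, was at 0.0533 and 0.0333 TPM, CD3E at 0.0167 and 0.0467 TPM, and the monocyte marker CD14 at 132 and 81.9 TPM. Of the 20 immune markers, 5 were at a mean of at least 1 TPM in some group of this line. These values argue against immune cells, and expression by Huh7 cells themselves is a hypothesis that was not tested further. Of markers of other cell types, picked after their values were seen, the endothelial PECAM1 was at 1.11 and 5.21 TPM in control and with disulfiram and ESAM at 1.08 and 2.97 TPM. The pericyte marker RGS5 was at 1.77 and 4.07 TPM. The endothelial VWF was at 0.103 and 0.0633 TPM and CDH5 at 0.0467 and 0.01 TPM. The source of these transcripts was not tested.

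A hypothesis that disulfiram moves the same genes with and without thalidomide was tested on separate libraries. Of the genes higher with disulfiram against control, 72.2% were also higher with the combination against thalidomide, as the hypothesis predicts. Independent lists would share 335 of 1340 genes and 968 were shared. That baseline may be too low, since 1 fit gave both comparisons the same estimate of spread per gene. Across all genes the log2 fold changes of these comparisons correlated at a Pearson's r of 0.599. A second hypothesis, that thalidomide moves the same genes with and without disulfiram, was tested by the correlation across genes of its changes against control and on disulfiram, which also use separate libraries. Pearson's r was -0.023 and Spearman's rho -0.058, and 0.06 and 0.10 after the GC correction. This decides nothing, as limma called 0 and 1 genes for these changes (873 and 2631 at an unadjusted p below 0.05) and they followed GC content in opposite directions (rho 0.20 and -0.64).

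For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every split but the real one also puts libraries of both groups on each side. A real difference then widens the spread within the sides and lowers the gene calls. The counts of the other splits are therefore not the numbers expected by chance. Genes called by the real split and by the highest other were 2034 and 1 for disulfiram against control, 3852 and 3 for the combination against control, 4946 and 2 for the combination against thalidomide and 2624 and 2 for disulfiram against thalidomide. In each of these 1 of 10 splits was as large. For thalidomide against control they were 0 and 2, with 10 of 10 as large since no count is below 0, and for the combination against disulfiram 1 and 3, with 8 of 10. Lists called were 20 and 16 for disulfiram against control, 17 and 14 for the combination against control and 17 and 14 for disulfiram against thalidomide, with 1 of 10 as large in each. They were 15 and 16 for the combination against thalidomide, with 2 of 10, 11 and 15 for thalidomide against control, with 5 of 10, and 5 and 8 for the combination against disulfiram, with 5 of 10.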
